A study of Mus musculus with 78 samples.

How the data were processed

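Total RNA of mouse striatum was measured on Illumina expression BeadChips with 6 arrays per slide, per the labels, from biotinylated cRNA. The deposited non-normalized table holds one intensity value per probe and array, on a linear scale, per the file headers. The deposited processed table holds log2 values whose array medians lie between 6.936 and 6.948. Neither the labels nor the headers give the software, the background correction or the normalization behind either table. Both hold 45281 probes for 78 arrays. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378, and the last 2 kinds were left unnamed. The labels number the withdrawal days 13, 15, 18 and 24, while the column headers of the signal table number them 1, 3, 6 and 12. With 12 injection days the numberings fit each other if the labels count from the first injection day and the headers from the last. That puts the withdrawal samples 1, 3, 6 and 12 days after the last injection day. The design text words the labelled days as days of withdrawal, so this interval is inferred and not stated, and the labelled days are used as names.

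The design set out before the data were examined called for background correction from detection p-values. The tables hold none, so its stated fallback was used, log2 of quantile-normalized intensities. The planned filter on detection p-values was replaced, after the files were seen, by one that kept probes above their array's median on all arrays of at least 1 of the 25 groups, which left 23810 probes. For each symbol the probe with the highest mean was taken, which gave 12371 genes, 5028 of them with more than 1 probe past the filter. Other probes of a gene can differ: Tnfrsf25 and Hif3a, for example, have a probe with a methamphetamine treatment change of -0.01 and 0.00.

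One linear model (limma 3.58.1 in R 4.3.3) was fitted to all 78 arrays with the mean of each of the 25 groups and a term for each of the 13 slides, 37 coefficients and 41 residual degrees of freedom. The slide layout follows from the array names in the labels, and 3 slides with 18 arrays come from another chip lot than the other 60 arrays. Each drug was compared with saline, and methamphetamine with heroin, as the mean over the 4 days of a phase. Further contrasts tested the drug effect in treatment minus that in withdrawal, its difference between the days of a phase (moderated F), and saline against naive. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Single-day counts use 3 arrays against 3 with the spread pooled over all groups.

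Genes to name were fixed before the data were examined. They are up to 12 per direction with the largest change among genes past the threshold that moved the same way on all 4 days for the drug comparisons, up to 5 per direction for the others, the 5 smallest p of each F test, up to 4 members of each list, and 12 genes chosen in advance. Where 5 or fewer genes passed all are named, and where none did the 3 with the smallest p. Mfsd2a, Xdh, Slc17a7, Ttr and the marker genes of the hippocampus were named after their values were seen. In the same way 27 gene lists were fixed, 17 of pathways and neuronal genes and 10 of cell types, and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Members are counted as past the threshold over all genes and adjusted over the list alone.

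Alternatives fixed beforehand were the deposited log2 values, no filter, all probes, no slide term, slide as a random block, array position as a term, lot 2 alone, the replicate number as a block, only the groups compared, robust trended variances, array weights and leaving out each of the 78 arrays in turn. Chosen after the data had been seen were normexp background correction with an offset of 50, median centring, a stricter filter, leaving out the methamphetamine day 1 arrays, leaving out the 4 arrays that the deposited table treats apart, and the deposited values without 1 averaged column. Those 4 are the methamphetamine day 1 arrays and saline withdrawal day 15 replicate 2. Fits of the signals without methamphetamine day 1 also left day 1 of heroin and saline out of the treatment means. The permutation of labels for list means (100000 permutations) and the hippocampal list were also chosen then, as was the simulation of unchanged groups without the methamphetamine day 1 arrays (50 simulations).

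The scripts were tested on simulated arrays with the spread of the real ones and 200 changed genes among 12371. For methamphetamine against saline in treatment, 96.5, 99 and 100% of genes changed by 0.3, 0.6 and 1 log2 units were recovered. For methamphetamine on day 3 the shares were 15.5, 84.5 and 98.5%, for heroin differences between treatment days 1.5, 66.5 and 97.5%, for saline against naive in treatment 81.5, 98 and 99.5%, and for the methamphetamine effect in treatment minus withdrawal 79.5, 99.5 and 99.5%.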

Results

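Striatal RNA of C57BL/6J mice was measured on 78 Illumina mouse expression arrays, 1 sample per array. The striatum is a deep forebrain region with dense dopamine input, and heroin and methamphetamine both raise dopamine there. Mice received methamphetamine (first dose 2 and last dose 8 mg/kg), heroin (first dose 10 and last dose 40 mg/kg) or saline, 2 injections a day over 12 days. Each drug and saline was sampled on treatment days 1, 3, 6 and 12 and on withdrawal days labelled 13, 15, 18 and 24, with 3 arrays per drug and day, so 12 per drug and phase. A further 6 arrays came from naive mice. The median signal per array ran from 95 to 184 intensity units, and the ratio of the 95th to the 5th percentile from 22.1 to 45.2. The number of arrays limits the precision. Nothing in the labels beyond the replicate numbers says whether replicates are separate animals. Log2 changes below are means over the 4 days of a phase, ± SE, with limma's adjusted p over 12371 genes and 12 arrays per group unless stated otherwise.

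Methamphetamine treatment against saline asks what repeated stimulant exposure changes in the striatum. Expression of the lipid droplet coat gene Plin4 (probe ILMN_2588249) rose by 0.84 ± 0.0988 (adjusted p = 7.53e-08), a fold of 1.79, higher on 9 of the 11 slides that hold both groups. The arrays of a phase on one slide come from different days, so slide counts and lot means, here and below, mix drug with day. The clock repressor gene Ciart rose by 0.59 ± 0.0523 (adjusted p = 2.31e-11, 9 of 11 slides), and the hypoxia-inducible factor gene Hif3a by 0.55 ± 0.0962 (adjusted p = 0.000197, 10 of 11 slides). Gfap, the intermediate filament of astrocytes, rose by 0.72 ± 0.0756 (adjusted p = 4.38e-09, 8 of 11 slides), with single-day values of 1.16, 0.20, 1.58 and -0.05 on days 1, 3, 6 and 12. Spink8, a Kazal-type protease inhibitor gene, rose by 1.10 ± 0.0778 (adjusted p = 1.17e-14, 11 of 11 slides), with 2.83 on day 1. Clspn, a replication checkpoint gene, fell by 0.52 (SE 0.0882, adjusted p = 0.000163, lower on 11 of 11 slides), and the sialyltransferase gene St8sia3 and the matrix protein gene Spon2 fell by 0.40 and 0.35. In all, 308 genes rose and 265 fell. Leaving out methamphetamine day 1 replicate 3 gave 308 genes in total, day 6 replicate 2 gave 368 and day 1 replicate 2 gave 953. Without the 3 methamphetamine day 1 arrays and with day 1 left out of the means, 42 genes passed, 26 higher and 16 lower. Plin4, Ciart, Hif3a, Gfap, Spink8, Clspn, St8sia3 and Spon2 were among them, with Spink8 at 0.54 and Plin4 at 1.12. The antigen presentation genes Cd74 and H2-Aa fell by 0.47 and 0.43 in the fit of all arrays and were at -0.38 and -0.35 without day 1, no longer past the threshold. On the 3 slides of chip lot 1 the mean difference was 0.28 for Plin4 and 0.52 for Ciart, and on the 8 slides of lot 2 it was 1.07 and 0.64.

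Of the 25 glucocorticoid-responsive genes, all measured, 13 rose during methamphetamine treatment and none fell (17 adjusted over the list alone), and camera placed the list above other genes (adjusted p = 2.39e-15, and adjusted p = 0.000614 with an estimated correlation, the highest of 9 settings from 5.82e-17 on). Besides Plin4 and Hif3a these included the kinase gene Sgk1 (0.37 ± 0.0886), the receptor cochaperone gene Fkbp5 (0.25 ± 0.0449) and the phagocytic receptor gene Mertk (0.23 ± 0.0416). Of 15 measured circadian clock genes, 6 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.011 with an estimated correlation, from 1.49e-11 over the settings). Per2 rose by 0.37 ± 0.0704 and Per1 by 0.28 ± 0.0711, while Arntl, which drives their transcription, fell by 0.21 (SE 0.0451). Among 11 reactive gliosis genes, Gfap, Serpina3n (0.47 ± 0.0613) and the complement gene C4b rose (4 higher and 1 lower adjusted over the list alone), with adjusted p = 0.108 with an estimated correlation, the only one of 9 settings not past the threshold (from 8.8e-06). Of 15 astrocyte markers, Gfap, the glutamate transporter gene Slc1a2 (0.29 ± 0.0436) and Aldoc rose (3 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation, and 0.000466 to 0.303 over 9 settings, 6 of them past the threshold). Of 9 interferon-stimulated genes Irf9 rose (7 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation). Of 16 medium spiny neuron genes, which mark the main striatal cell type, Rgs9 and Pde10a fell by 0.53 and 0.40 (16 lower adjusted over the list alone; adjusted p = 0.253 with an estimated correlation). The mean of that list was -0.98 on day 1 and between -0.12 and 0.07 on days 3, 6 and 12, and Rgs9 was at -0.14 without day 1. Of 18 glutamate and GABA receptor genes, Gria1 and Grin2a rose and Grm4 and Gabrd fell (2 higher and 3 lower adjusted over the list alone), and none of these passed without day 1.

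Methamphetamine day 1 stood apart from the other days. The list of 19 measured hippocampal markers, written after these genes had been noticed, scored 1.04, 0.787 and 1.46 log2 units above the median array on the 3 methamphetamine day 1 arrays and at most 0.19 on the other arrays. The 13 of them not seen before listing scored less, 0.558, 0.398 and 0.926, and at most 0.17 on the other arrays. The dentate gyrus gene C1ql2 was 3.93, 3.42 and 4.51 log2 units above the day 1 saline mean on replicates 1, 2 and 3. The dopamine receptor gene Drd1 was at -1.09, -0.73 and -3.91 against the same mean. The cortical excitatory neuron list was also high on these arrays, at 0.931, 0.7 and 1.03, and the choroid plexus list was at -0.468, 0.806 and 1.54. Day 1 alone gave 416 higher and 478 lower genes, against 0, 7 and 3 genes on days 3, 6 and 12. With 3 arrays against 3 on 1 day, limma found 459 genes at an unadjusted p under 0.05 on day 3. Leaving out methamphetamine day 1 replicate 3 gave 230 genes for day 1 and leaving out replicate 2 gave 1352.

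**Figure D1:**
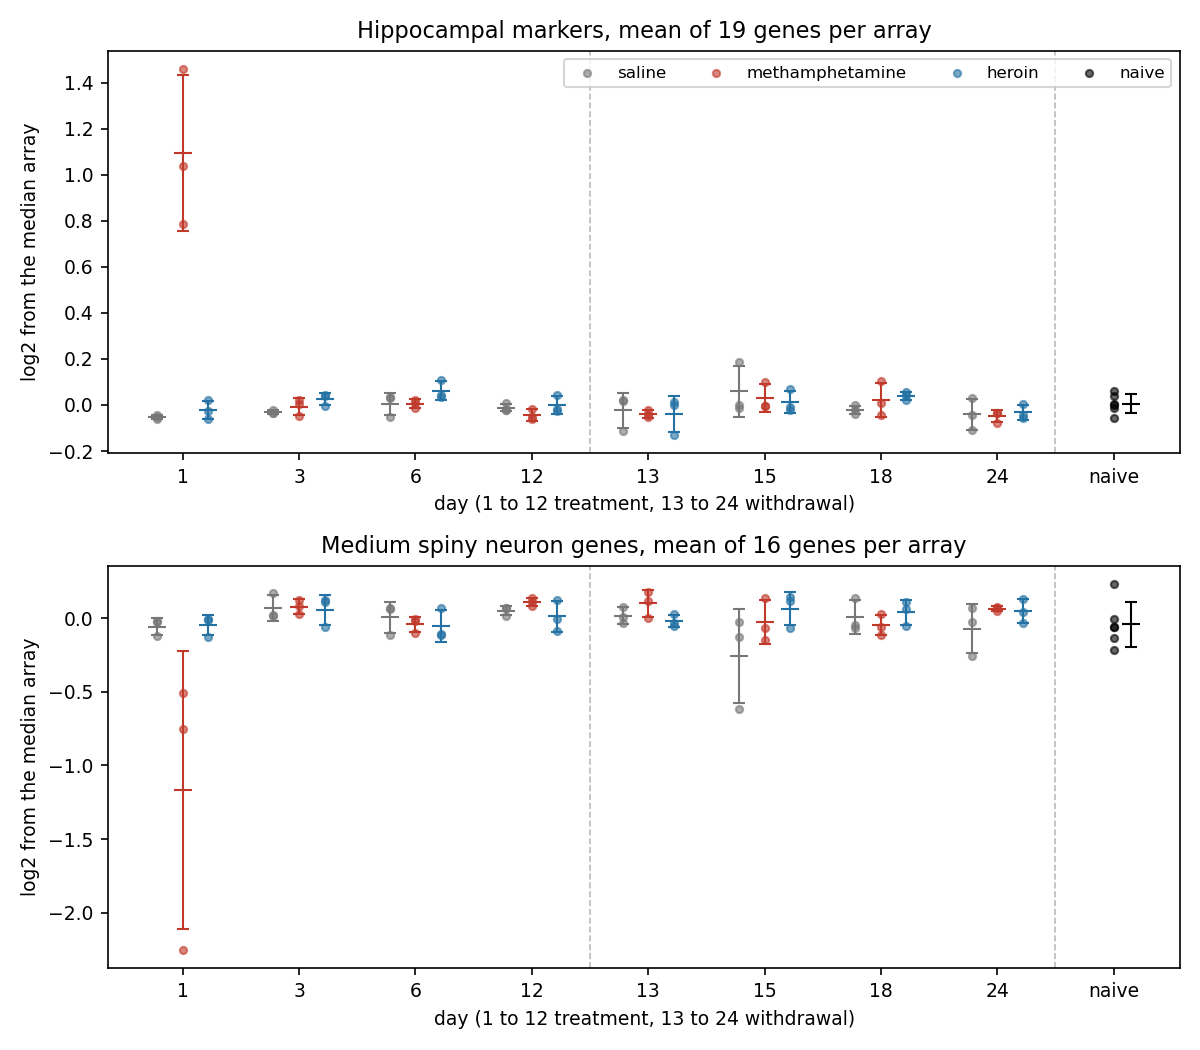
Each point is 1 of the 78 arrays, by drug and day. The vertical axes give the mean log2 deviation of the 19 hippocampal markers and of the 16 medium spiny neuron genes from the median array, and the 3 methamphetamine day 1 arrays lie at 1.04, 0.787 and 1.46 for the first list. That list includes genes noticed on these arrays before it was written.

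Heroin treatment against saline asks the same of an opioid. Plin4 rose by 1.21 ± 0.0988 (adjusted p = 1.48e-12), a fold of 2.31, higher on 11 of 11 slides. Sult1a1, a phenol sulfotransferase gene, rose by 0.63 ± 0.0688 (adjusted p = 1.62e-08, 11 of 11 slides), Hif3a by 0.72 ± 0.0962 and Sgk1 by 0.61 ± 0.0886. Ciart rose by 0.66 ± 0.0523 (adjusted p = 7.61e-13, 10 of 11 slides), the clock output gene Dbp by 0.35 ± 0.0564 and the integrin subunit gene Itgad by 0.40 ± 0.0459. Spink8 rose by 0.61 ± 0.0778 (adjusted p = 8.93e-07, 10 of 11 slides). The water channel gene Aqp4 fell by 0.23 (SE 0.0395, lower on 11 of 11 slides), the clock activator gene Arntl by 0.28 (SE 0.0451), and the class II antigen gene H2-Ab1 by 0.40 (SE 0.108, adjusted p = 0.0407). The Aqp4 value is that of 1 probe, and the other probe of the gene stood at -0.02. In all, 124 genes rose and 81 fell, a count that moved with the slide term, the chip lot and array weights, as given below. Lot means were 1.26 and 1.23 for Plin4 and 0.61 and 0.60 for Ciart on lots 1 and 2. Leaving out heroin day 12 replicate 3 gave 108 genes and leaving out heroin day 1 replicate 1 gave 122.

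Of the 25 glucocorticoid-responsive genes, 12 rose with heroin and none fell (18 adjusted over the list alone). The list's adjusted p was 1.94e-27 by camera and 3.03e-06 with an estimated correlation, and between 3.17e-34 and 2.52e-05 over 9 settings. Of 15 clock genes, Ciart, Dbp, Bhlhe40, Per3 and Nr1d1 rose and Arntl fell (8 and 2 adjusted over the list alone; adjusted p = 0.00344 with an estimated correlation, from 2.47e-07). Of 18 heat shock chaperone genes, Cryab fell by 0.31 (SE 0.0596; 6 lower adjusted over the list alone; adjusted p = 0.0189 with an estimated correlation, from 2.85e-08). Of 16 endoplasmic reticulum stress genes, the chaperone gene Hsp90b1 fell by 0.19 and the disulfide isomerase gene Creld2 by 0.18 (7 lower adjusted over the list alone; adjusted p = 0.0302 with an estimated correlation, and 4.3e-06 to 0.0483 over the settings). A test that permuted drug and saline labels within days, chosen after the data were seen, gave a mean difference of 0.256 for the glucocorticoid list (adjusted p = 0.00027, from 1e-05, the smallest p its permutations can give), 0.138 for the clock list (adjusted p = 0.000405), -0.0865 for the endoplasmic reticulum list (adjusted p = 0.00333) and -0.0831 for the heat shock list (adjusted p = 0.205). For methamphetamine the same permutation test gave 0.189 for the glucocorticoid list (adjusted p = 0.00054) and 0.137 for the clock list (adjusted p = 0.0144). It also gave 0.171 for the gliosis list (adjusted p = 0.0153) and 0.0948 for the astrocyte list (adjusted p = 0.0314), and without day 1 0.168 (adjusted p = 0.0589) and 0.0727 (adjusted p = 0.209). For the endoplasmic reticulum list it gave -0.046 with methamphetamine (adjusted p = 0.29), and -0.092 without day 1 (adjusted p = 0.0105). Of 5 blood markers, which trace another tissue, none passed over all genes with heroin and 4 were higher adjusted over the list alone. Their camera adjusted p was 0.242 with an estimated correlation, and 8.95e-05 to 0.494 over 9 settings, 5 of them past the threshold. The permutation mean of the blood list was 0.255 (adjusted p = 0.223), and 0.348 without day 1 (adjusted p = 0.0856). The opioid peptide genes Penk and Pdyn stood at 0.11 ± 0.15 and 0.27 ± 0.121 with heroin and did not pass. The immediate early genes Fos and Arc stood at -0.23 ± 0.126 and -0.16 ± 0.14 and did not pass either.

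**Figure D2:**
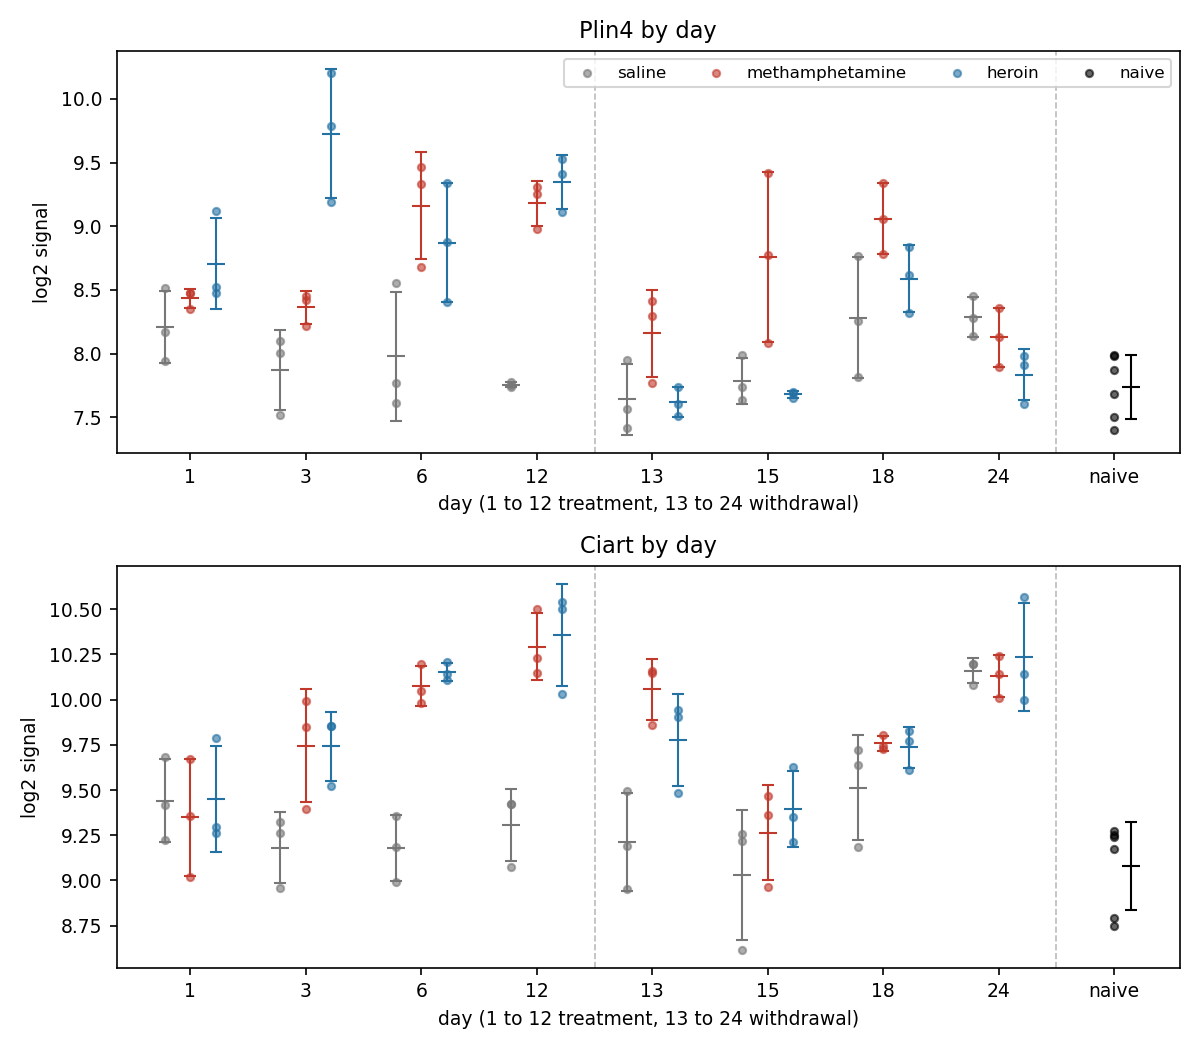
Points are single arrays, by drug and day, with log2 signal on the vertical axis for Plin4 and Ciart, and the marks with bars give group means and SD. Treatment means over 12 arrays were 8.78, 9.16 and 7.95 for Plin4 and 9.87, 9.93 and 9.28 for Ciart with methamphetamine, heroin and saline.

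Both drugs raised 47 genes and lowered 30 during treatment, counted as genes past the threshold in each comparison. Plin4, Hif3a, Ciart, Sult1a1, Spink8, Dbp, the lysolipid transporter gene Mfsd2a and the purine oxidase gene Xdh rose with both, and also passed in both without day 1. Both comparisons share their saline arrays. Groups simulated with no drug effect and the same sharing of controls gave 0 shared genes in each direction. With no effect few genes can pass in either comparison, so this does not show how many shared genes the common controls add. Independent lists of the same lengths would share 3.09 and 1.74. With the saline arrays split between the comparisons, medians of 6.5 and 0 genes were shared, and the median correlation of the log2 changes was 0.168. Without the methamphetamine day 1 arrays, and with day 1 left out of both drugs' means, the shared genes were 17 higher and 6 lower. Groups simulated for those arrays, again with no drug effect, gave 0 and 0, with the same limit. Across the genes of the fit of all arrays, which are not independent replicates, the log2 changes of both drugs had a correlation of 0.452 and a covariance of 0.00261, against 0.501 (SD 0.129) and 0.00134 for the simulated groups, a covariance difference of 0.00127. Without day 1 they were 0.631 and 0.00409, against 0.527 (SD 0.167) and 0.00259. In both fits the correlation lies within 1 SD of the simulated one, so by itself it does not part a likeness of the drugs from the shared controls.

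The direct comparison of methamphetamine with heroin asks where the drugs part. During treatment Gfap was higher with methamphetamine by 0.70 ± 0.0756 (adjusted p = 2.99e-08, 9 of 11 slides), and Aqp4 and Slc1a2 by 0.23 ± 0.0395 and 0.21 ± 0.0436. The other Aqp4 probe hardly parted the drugs, at 0.02 with methamphetamine and -0.02 with heroin, each against saline. Plin4 was lower with methamphetamine at -0.37 ± 0.0988 (7 of 11 slides; lot means -0.98 and -0.06), Sult1a1 at -0.35 ± 0.0688 and the cell cycle inhibitor gene Cdkn1a at -0.28 ± 0.0697. The zinc finger gene Zfp941 was lower at -0.32 ± 0.044 (adjusted p = 4.92e-06). In all, 238 genes were higher and 192 lower, with 231 in total without methamphetamine day 1 replicate 3, 256 without heroin day 12 replicate 3 and 863 without methamphetamine day 1 replicate 2. Of the 25 glucocorticoid-responsive genes 5 were lower with methamphetamine (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.364 with an estimated correlation), and of 14 microglia markers Ctss, Fcrls and P2ry12 were higher (3 adjusted over the list alone; adjusted p = 0.208 with an estimated correlation). Of 5 blood markers, the globin genes Hba-a1 and Hbb-bt were lower (5 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation). Without methamphetamine day 1, 9 genes passed, among them Gfap at 0.47 and Zfp941 at -0.27, and Plin4, Sult1a1, Cdkn1a, Aqp4 and Slc1a2 did not.

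The withdrawal comparisons ask which changes outlast the drug. With methamphetamine 3 genes passed, all higher. They were Plin4 (0.51 ± 0.0988, adjusted p = 0.0238, 8 of 11 slides), Ciart (0.32 ± 0.0523, adjusted p = 0.00199, 8 of 11 slides) and Dbp (0.29 ± 0.0564, adjusted p = 0.0238, 10 of 11 slides). With heroin 6 genes passed, all higher: Per1 (0.35 ± 0.0711), the small GTPase gene Rem2 (0.33 ± 0.07), Ciart (0.32 ± 0.0523), the triglyceride synthesis gene Dgat2 (0.26 ± 0.0494), Coq10b (0.23 ± 0.0473) and the mitochondrial carrier gene Slc25a25 (0.22 ± 0.0456), each higher on 7 to 10 of 11 slides. Leaving out 1 array left 1 gene with heroin for 7 different arrays, and 64 genes without heroin day 13 replicate 1. With methamphetamine it left 1 gene for 6 different arrays and 5 genes without methamphetamine day 18 replicate 1. Ciart stood at 0.81 and 0.42 on day 13 and at -0.07 and 0.18 on day 24 with methamphetamine and heroin, each ± 0.14 with 3 arrays per group. The smaller differences on day 24 went with a higher saline signal, not with lower drug signals. Saline arrays were at 8.95, 9.49 and 9.19 on day 13 and at 10.2, 10.2 and 10.08 on day 24. Methamphetamine arrays were at 9.86, 10.16 and 10.15, then 10.01, 10.14 and 10.24, and heroin arrays at 9.48, 9.94 and 9.91, then 10.00, 10.57 and 10.14. Methamphetamine and heroin differed in Plin4 (0.59 ± 0.0988 higher with methamphetamine, adjusted p = 0.00317, 11 of 11 slides), with lot means of 0.96 and 0.39. Mean Plin4 signals in withdrawal were 8.53, 7.93 and 8.00 log2 units with methamphetamine, heroin and saline. On days 15 and 18 every methamphetamine array was above every saline array for Plin4, and on day 13 the groups overlapped. On day 24 Plin4 was at 7.90, 8.36 and 8.13 with methamphetamine and at 8.14, 8.45 and 8.28 with saline. The methamphetamine rise of Plin4 was thus not seen on day 24. Of 12 late activity-regulated genes none passed between methamphetamine and heroin and 1 was lower adjusted over the list alone, with adjusted p = 0.0257 with an estimated correlation, from 4.59e-06 over the settings, and a permutation mean of -0.0943 (adjusted p = 0.18). Of 15 clock genes 2 rose with each drug (5 adjusted over the list alone), with an adjusted p of 0.00573 for methamphetamine and 0.0282 for heroin with an estimated correlation (from 1.1e-06 and 2.21e-05 over the settings). The permutation of labels gave 0.0883 (adjusted p = 0.149) and 0.101 (adjusted p = 0.0289) for this list. Of 9 interferon-stimulated genes none passed over all genes with methamphetamine and 8 were higher adjusted over the list alone (camera adjusted p = 1.28e-13, and adjusted p = 0.00573 with an estimated correlation, from 4.65e-20 over the settings). The mean of that list was 0.0644 on chip lot 1 and 0.273 on lot 2, higher on 10 of 11 slides. Of 14 microglia markers none passed with methamphetamine in withdrawal, over all genes or adjusted over the list alone (adjusted p = 0.224 with an estimated correlation, and 0.00281 to 0.363 over 9 settings, 6 of them past the threshold). The 25 glucocorticoid-responsive genes included 1 gene past the threshold with each drug, Plin4 with methamphetamine (adjusted p = 0.1 with an estimated correlation) and Per1 with heroin (adjusted p = 0.965 with an estimated correlation). With the slide term limma gave 689, 1348 and 833 genes at an unadjusted p under 0.05 for methamphetamine, heroin and their direct comparison, and without it 0 genes passed in each of the 3.

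Within withdrawal, heroin on day 15 gave 26 higher and 123 lower genes against saline of the same day, with 3 arrays against 3. The cortical excitatory neuron markers averaged -1.16 ± 0.294 on that day, and the vesicular glutamate transporter gene Slc17a7 had log2 signals of 9.13, 9.86 and 10.3 with heroin and 11.4, 12.3 and 10.9 with saline. The choroid plexus and ependyma markers separated the same groups, with scores of -0.0453, 0.0163 and 0.0436 with heroin and 0.786, 0.956 and 0.963 with saline. Of these markers Ttr, a thyroid hormone carrier gene, had log2 signals of 11.44, 11.23 and 10.93 with heroin and 14.92, 15.16 and 15.19 with saline. Without heroin day 15 replicate 2, or without saline day 15 replicate 2, limma called 0 genes, without saline replicate 1 it called 1, without heroin replicate 1 it called 3, and without saline replicate 3 it called 298. The other single withdrawal days gave at most 2 genes with either drug, and heroin day 13 went from 0 to 26 genes without heroin day 13 replicate 3.

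The test of treatment against withdrawal asks whether a drug effect depends on continued dosing. For heroin 7 genes had a larger effect during treatment, among them Plin4 (difference 1.29 ± 0.139, adjusted p = 3.63e-08), Hif3a (0.75 ± 0.136), Sult1a1 (0.64 ± 0.097), Ciart (0.35 ± 0.0737) and Arrdc2 (0.33 ± 0.0661). For methamphetamine 44 genes differed, 35 with a higher and 9 with a lower effect during treatment, led by Spink8 (0.88 ± 0.11), C1ql2 (0.86 ± 0.156) and Gfap (0.73 ± 0.107). Without the methamphetamine day 1 arrays, and with day 1 left out of all treatment means, 1 gene passed for methamphetamine and 23 for heroin. The heroin count thus rests on treatment days 3, 6 and 12. C1ql2 was then at -0.08 for methamphetamine. Leaving out 1 array gave 24 to 377 genes for methamphetamine and 4 to 32 for heroin. The methamphetamine effect differed between treatment days for 136 genes, led by the dentate and CA1 genes C1ql2, Lct and Fibcd1, and for 2 genes without day 1. For heroin treatment, methamphetamine withdrawal and heroin withdrawal the between-day F test of limma called 0 genes (507, 587 and 881 at an unadjusted p under 0.05), with Ciart (range over days 1.06), the globin gene Hbb-bs (2.51) and Ext1 (1.19) at the smallest p of each.

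**Figure D3:**
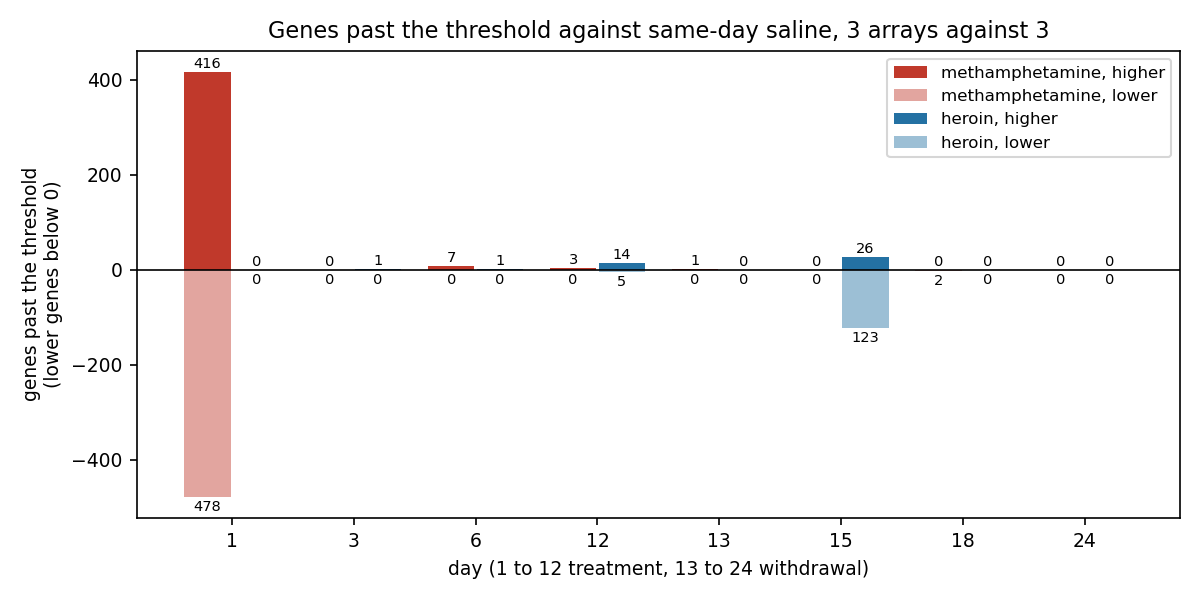
Bars give the number of genes past the threshold for each drug against saline on each day, higher above and lower below 0, with 3 arrays per group. The tallest bars are methamphetamine day 1, with 416 higher and 478 lower, and heroin day 15, with 26 higher and 123 lower.

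Saline against naive mice asks about the background of injection and handling, which slide position confounds here. In the treatment phase 5 genes rose: the immediate early genes Fos (1.01 ± 0.16, adjusted p = 0.00106), Npas4 (0.70 ± 0.129) and Dusp1 (0.48 ± 0.1), the stress-response gene Gadd45g (0.29 ± 0.0573) and the kinase subunit gene Pik3ca (0.28 ± 0.0573), with 12 saline and 6 naive arrays. In withdrawal 13 genes rose and 8 fell, led by Fos (1.37 ± 0.16, adjusted p = 3.37e-07), Arc (0.97 ± 0.178), Npas4 (0.89 ± 0.129), Dusp1 (0.70 ± 0.1) and Junb (0.65 ± 0.118), while Arntl fell by 0.26 (SE 0.0572). Of 17 immediate early genes 3 rose in treatment and 6 in withdrawal (6 and 10 adjusted over the list alone), with an adjusted p of 0.0795 and 0.00918 with an estimated correlation. All 6 naive arrays lay at the same slide position and on chip lot 2. With position as a further term 0 genes passed in either phase. Fos, Npas4 and Dusp1 in treatment were then at -0.51, -0.19 and -0.52, each with a limma adjusted p of 0.999. Treatment saline arrays lay only at positions A to C and naive arrays only at F, so in treatment that fit separates position from injection poorly. Neither the lost calls nor the changed signs decide between them there. Withdrawal saline arrays lay at positions C to F, and with 0 genes passing there too a difference apart from position is not shown. The larger count, 21 genes against 5, came in withdrawal, after the 12 injection days. The comparison therefore does not isolate injection.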

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

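All tests of explanations in this part, and the splits of the sample labels, were chosen after the results had been seen.

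The drug effect differed between treatment and withdrawal for 44 genes with methamphetamine and 7 with heroin, by a test of the difference itself. With methamphetamine the treatment effect exceeded the withdrawal effect by 0.88 for Spink8, 0.86 for C1ql2, 0.73 for Gfap, 0.71 for the anion exchanger gene Slc26a4 and 0.65 for the death receptor gene Tnfrsf25. It was lower by a difference of -0.44 for Neu2, -0.38 for Pdzph1, -0.35 for the chemokine receptor gene Ccr6, -0.34 for Sgpp2 and -0.33 for Tpbgl. Without methamphetamine day 1 only 1 gene passed for methamphetamine, and C1ql2 was at -0.08. With heroin the difference was 1.29 for Plin4, 0.75 for Hif3a, 0.64 for Sult1a1, 0.35 for Ciart and 0.33 for Arrdc2. The methamphetamine effect differed between treatment days for 136 genes, with ranges over days of 2.18 for Fibcd1, 2.62 for Lct, 3.92 for C1ql2, 1.42 for St6galnac5 and 2.01 for Olfml2b. Without day 1 that test passed 2 genes, and leaving out 1 array gave 54 to 411. Among the 6 naive arrays, replicate 3 lay far from the others for Dusp1, with a gap of 0.696 of the range, the largest among 12 genes checked; a gap over the critical value used is met by chance in about 1 in 20 groups per gene. Of 3863 tested probes without a single gene symbol, which the comparisons leave out, 112 passed for methamphetamine treatment, 33 for heroin treatment and 1 for heroin withdrawal.

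The first pattern weighed is methamphetamine day 1, where dentate and CA1 genes were higher and medium spiny neuron genes lower on all 3 arrays. Against a single aberrant array as the whole cause stands the lowest count of 230 genes with any 1 of the 6 arrays left out, and against the slides stands the highest hippocampal score of 0.11 among the other arrays of the same slides. Hippocampal tissue in these samples is a candidate explanation: the median change of the 13 listed markers not seen before the list was written was 0.535, all 13 were higher, and 6 passed. C1ql2 and Spink8, the most changed of the list, averaged 8.69 and 8.71 log2 units over all arrays, none of the 19 measured markers stands on another list, the cortical list was high on the same arrays (0.931, 0.7 and 1.03), and how much the striatum itself expresses them was not tested. An effect of the first injections stays open as untested, since these 3 arrays are the whole group.

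The second pattern is heroin day 15, with 123 of 149 genes lower. Cortical tissue in saline replicate 2 alone is argued against, since the cortical list stayed at -1.05 ± 0.322 without that array (-1.16 ± 0.294 with it). Without it 0 genes passed. All 149 genes kept their direction, with a median size of 0.628 in place of 0.734 and a median SE of 0.193 in place of 0.18. They were chosen from these same arrays, so the kept direction and the smaller size are no test. Without the slide term the median size was 0.502 and the SE 0.169. Part of that fall also follows from the choice of genes, so whether the slide adjustment accounts for some of the pattern stays open. Cortical or choroid plexus tissue in different amounts in several samples of the day (the choroid plexus list averaged -1.12 in heroin minus saline), and an effect of heroin withdrawal, stay open as untested; the cortical list was at 0.473 ± 0.231 in day 15 saline and -0.69 ± 0.233 in day 15 heroin, each minus naive.

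The third pattern is the rise of glucocorticoid-responsive genes with both drugs. Low values in the shared saline controls are argued against, since the list stood at 0.0302 ± 0.0326 in saline minus naive, against 0.255 ± 0.0257 for heroin and 0.193 ± 0.0257 for methamphetamine minus saline, although all naive arrays share 1 slide position. The methamphetamine day 1 samples are argued against too, since the list stood at 0.217 ± 0.0347 without them. A drug effect on stress hormone signalling may account for it, as a hypothesis, and hormone levels and the time from injection to dissection are not given in the sources used here.

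Sample labels were reassigned at random in 100 splits each, the real one included, within days for the drug comparisons, across the days of a phase for the between-day tests, and between saline and naive arrays for those comparisons. These splits change which drugs share a slide while the fit keeps its slide term, which may favour the real labels. With that limit, a chance division is unlikely for heroin treatment (1 split as large, 205 genes against at most 12). The same holds for methamphetamine treatment (1 split, 573 against 268) and methamphetamine against heroin in treatment (1 split, 430 against 169). Both counts rest largely on methamphetamine day 1: without it they were 42 and 9, for which no splits were run. For methamphetamine withdrawal (1 split, 3 against 1) chance is not excluded, since leaving out 1 array could lower the 3 genes to 1. The share of splits as large was also under 0.05 for heroin withdrawal (2 splits, 6 against 11). The same held for methamphetamine against heroin in withdrawal (3 splits, 1 against 3). It held too for the phase differences of methamphetamine (2 splits, 44 against 92) and heroin (3 splits, 7 against 12). In each of these another split called more genes than the real labels, so chance is less likely there but not excluded. Without the slide term 0 genes passed in each withdrawal comparison, and without methamphetamine day 1 the 44 genes became 1. For saline against naive in treatment the share was under 0.05 too (2 splits, 5 against 95), but the split with 95 genes points to a structure of the samples. With position as a term 0 genes passed there, in a fit that separates position from group poorly. Chance cannot be excluded either for the methamphetamine differences between treatment days (7 splits, 136 against 955) and saline against naive in withdrawal (5 splits, 21 against 484), where a split calling several times the real count points to a structure of the samples. The other between-day tests gave 0 genes, so all 100 splits were as large, with at most 1, 5 and 55 genes for heroin treatment, methamphetamine withdrawal and heroin withdrawal. The number of lists past the threshold was also split. In methamphetamine against heroin in treatment (1 split, 16 against 15) and heroin withdrawal (1 split, 9 against 8) no other split was as large. Yet the other splits there gave medians of 6 and 3 lists, and with an estimated correlation the real counts are 0 and 1. Chance is therefore not excluded for them. Nor is it for methamphetamine treatment (23 splits, 9 against 13), heroin treatment (30 splits, 6 against 10), methamphetamine withdrawal (8 splits, 9 against 11) and methamphetamine against heroin in withdrawal (8 splits, 7 against 9). Single days have only 10 splits, too few to judge. Methamphetamine day 1 gave 894 genes against at most 341 in another split, day 6 gave 7 against 0, day 12 gave 3 against 0, day 13 gave 1 against 0 and day 18 gave 2 against 16, where 4 splits were as large. Heroin day 15 gave 149 against 2, day 12 gave 19 against 0, and days 3 and 6 gave 1 against 0 each. The 19 genes of heroin day 12 became 2 without heroin replicate 3, 3 without saline replicate 2 and 10 without saline replicate 1, and the gene of day 3 was lost without heroin replicate 1. With methamphetamine, day 6 fell to 4 genes without saline replicate 2 or methamphetamine replicate 3. Day 13 fell to 0 without methamphetamine or saline replicate 1 and rose to 2 without saline replicate 3. Day 18 fell to 0 without methamphetamine replicate 1, saline replicate 2 or saline replicate 3. On the remaining single days no gene passed and all 10 splits were as large, yet heroin day 13 gave 26 genes without heroin replicate 3, heroin day 1 gave 4 without saline replicate 1 and methamphetamine day 15 gave 1 without saline replicate 1.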

How the results depend on the processing

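Values below are genes past the threshold unless stated otherwise. Background correction from detection p-values, and the variants built on it, were not run because the tables hold no detection p-values.

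Without the slide term the counts were 144 for methamphetamine treatment, 48 for heroin treatment and 102 for methamphetamine against heroin, with 0 in each withdrawal comparison. The phase difference was 19 for methamphetamine and 3 for heroin, the methamphetamine day test 501, the heroin withdrawal day test 1, and saline against naive 0 and 6 in treatment and withdrawal. With slide as a random block (correlation 0.382) the methamphetamine day test gave 426 and saline against naive in withdrawal 12. With position as a term the counts were 322 for methamphetamine treatment, 1 and 1 for methamphetamine and heroin withdrawal, 27 and 11 for the phase differences, 78 for the day test, and 0 and 0 for saline against naive. Position turned Fos to -0.5058, Npas4 to -0.1906 and Dusp1 to -0.5216 in saline against naive in treatment, Fos to -0.04822 in methamphetamine treatment, and Fos to -0.01294 and Arc to -0.05221 in methamphetamine withdrawal. For saline against naive in treatment that fit separates position from group poorly.

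On chip lot 2 alone the counts were 167, 37 and 96 for methamphetamine treatment, heroin treatment and their comparison, 1, 0 and 0 in withdrawal, 9 and 2 for the phase differences, 44 for the day test and 1 for saline against naive in treatment. Pdyn turned to -0.03026 in methamphetamine treatment and Fos to -0.02769 in methamphetamine withdrawal. With only the groups compared in the fit, methamphetamine treatment gave 83, its withdrawal 8, the phase difference 28, the treatment day test 2 and the withdrawal day test 5, and Cdkn1a in methamphetamine withdrawal was 0.02806. Array weights gave 1353, 535 and 1074 for the treatment comparisons, 7 and 14 for methamphetamine and heroin withdrawal, 318 and 49 for the phase differences, 301 and 1 for the methamphetamine and heroin treatment day tests, and 3 and 9 for saline against naive.

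With the replicate number as a block, a paired fit, the heroin phase difference gave 19 and saline against naive 0 and 0, and Fos in methamphetamine treatment was -0.007313. The numbers are not taken to pair arrays: signals with the same number in different groups had a mean correlation of -0.0105 against 0.00537 for different numbers, and 258 of 828 such pairs were over 0.1. Of 72 arrays 36 best match an array of their own number, more than 3 numbers would give at random, which is a hint from the data and not the design.

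Without a filter the heroin phase difference gave 4, and with the stricter filter 16. Testing every probe gave 673 for methamphetamine against heroin, 5 and 10 for methamphetamine and heroin withdrawal, 89 for the methamphetamine phase difference, 223 for the day test and 3 for saline against naive in treatment. Median centring gave 27 and 4 for the phase differences and 8 for saline against naive in withdrawal, and Drd1 in heroin treatment was 0.02951.

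The deposited processed values gave 69 for methamphetamine treatment, 19 for methamphetamine against heroin, 10 for heroin withdrawal, 1 and 14 for the phase differences, 1 for the day test, and 0 and 0 for saline against naive. The last counts follow from how that table equates saline and naive means. Its methamphetamine day 1 columns, as differences from saline, are set against each other. Replicate 1 has weights of 0.49 and -0.51 on the signals of replicates 1 and 2, replicate 2 has -0.51 and 0.49, and replicate 3 has -0.014 on each. This removes most of the day 1 difference by construction, so counts and signs that rest on it are no check. Day 15 columns carry those signals at 0.17, or -0.34 for saline replicate 2. The lists past the threshold numbered 8 for methamphetamine against heroin in treatment and 4 for methamphetamine withdrawal. In methamphetamine treatment Zfpm2 was -0.0006573, Penk 0.09448, Drd1 0.04495 and Drd2 0.0008088; against heroin Jun was -0.02362, Dusp4 -0.01776 and Serpina3n -0.01597; in the phase difference C1ql2 was -0.2888 and Slc26a4 -0.07364. In saline against naive Gadd45g was -0.00506 in treatment, and Junb -0.005892, H2ac12 0.003109 and Arntl 0.0224 in withdrawal. With the averaged column left out too, counts were 50 for methamphetamine treatment, 15 against heroin, 0 and 12 for the phase differences, 1 for the day test, and 0 and 0 for saline against naive. Zfpm2 was then -0.002911, Penk 0.1101, Drd1 0.04696, Drd2 0.004027, Jun -0.02423, Dusp4 -0.02158, Serpina3n -0.01332, C1ql2 -0.2923, Slc26a4 -0.06601, Gadd45g -0.004829, Junb -0.005699, H2ac12 0.00345 and Arntl 0.02237.

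Without the methamphetamine day 1 arrays, day 1 was left out of all treatment means. The counts were then 42 for methamphetamine treatment, 9 against heroin, 1 and 23 for the phase differences and 2 for the day test. Grin2a was -0.04446, Cdkn1a 0.04391, Penk 0.08822 and Drd1 0.004662 in methamphetamine treatment, Jun -0.0743 and Inhba 0.01028 against heroin, and C1ql2 -0.07771 in the phase difference. The fit without the 4 arrays that the deposited table treats apart also had no day 1 in its treatment means. Its counts were 50, 133 and 7 for the treatment comparisons and 6 and 11 for methamphetamine and heroin withdrawal. They were 1 and 14 for the phase differences and 2 for the day test, and 9 lists passed for methamphetamine against heroin in treatment. Grin2a was -0.04083, Cdkn1a 0.03996, Penk 0.096, Drd1 0.01518, Jun -0.06702, Inhba 0.005987 and C1ql2 -0.1587.

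With an estimated correlation the lists past the threshold numbered 2 for methamphetamine treatment, 0 against heroin, 2 and 1 for methamphetamine and heroin withdrawal, and 1 for their comparison. With the 4 arrays also left out they numbered 3, 1, 2, 2 and 1 in the same order. With fry they numbered 2 and 2 for methamphetamine and heroin withdrawal and 1 for their comparison.

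Leaving out 1 array at a time gave 308 (methamphetamine day 1 replicate 3) to 953 (day 1 replicate 2) for methamphetamine treatment, and 231 to 863 with the same arrays against heroin. Heroin treatment ran from 108 (heroin day 12 replicate 3) to 237. The phase difference ran from 24 to 377 (methamphetamine day 1 replicate 2) for methamphetamine and from 4 to 32 (heroin day 13 replicate 1) for heroin. The methamphetamine day test ran from 54 to 411, the heroin treatment day test from 0 to 1, the methamphetamine withdrawal day test from 0 to 0 and the heroin one from 0 to 2. Methamphetamine withdrawal ran from 1 to 5, heroin withdrawal from 1 to 64 (heroin day 13 replicate 1), and their comparison from 1 to 3. Saline against naive ran from 1 (naive 1 or 6) to 9 (naive 3) in treatment and from 11 (naive 4) to 23 in withdrawal.

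Genes near 0 changed sign between single-array fits. In methamphetamine treatment Fos ran from -0.09673 to 0.104 and Pdyn from -0.1032 to 0.2016, and in heroin treatment Drd1 from -0.06712 to 0.04259 and Drd2 from -0.09059 to 0.01291. In methamphetamine withdrawal Fos ran from -0.008263 to 0.1021, Arc from -0.03591 to 0.07275 and Cdkn1a from -0.06474 to 0.03294, and in heroin withdrawal Tsc22d3 from -0.06378 to 0.02152. No named gene with a changed sign was past the threshold in that alternative.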

Other observations

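Apart from the camera tests and the single-gene changes, the tests in this part were chosen after the results had been seen. Camera and the single-gene comparisons were fixed beforehand, but the camera settings that leave out arrays were also chosen later.

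The mean difference of interferon-stimulated genes between methamphetamine and saline was 0.162 in treatment (adjusted p = 0.0397, permutation of labels within days) and 0.252 in withdrawal (adjusted p = 0.0335). The lot means were 0.034 and 0.201 in treatment on chip lots 1 and 2. By camera the treatment shift has adjusted p = 0.253 with an estimated correlation, from 8.01e-07 over 9 settings. For heroin the permutation means were 0.00721 in treatment (adjusted p = 0.993) and 0.13 in withdrawal (adjusted p = 0.167), and camera passed the list in heroin withdrawal in 6 of 9 settings (4.02e-05 to 0.344). Among single genes Irf9, a subunit of the interferon-activated transcription factor complex, rose in methamphetamine treatment by 0.21 ± 0.0608. Opioid system genes had a permutation mean of 0.125 in heroin treatment (adjusted p = 0.0645) and 0.139 in heroin withdrawal (adjusted p = 0.167). With methamphetamine in treatment it was -0.0733 (adjusted p = 0.898), and 0.149 without day 1 (adjusted p = 0.0407). By camera this list passed in 1 of 9 settings in each drug's treatment comparison, with a highest adjusted p of 0.72 for methamphetamine and 0.654 for heroin. In heroin treatment the chromatin regulator gene Hdac5 fell by 0.14 (SE 0.0367) and the oligodendrocyte precursor gene Gpr17 by 0.24 (SE 0.05).

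Tissue markers varied between arrays, some of them arrays of the patterns above, where the choroid plexus list also set day 15 saline apart from day 15 heroin. The choroid plexus and ependyma list reached 1.77 on saline treatment day 3 replicate 2, 1.54 on methamphetamine day 1 replicate 3 and 1.29 on naive replicate 4. The blood list ran from -0.952 on methamphetamine withdrawal day 18 replicate 3 to 0.883 on heroin treatment day 6 replicate 2. The medium spiny neuron list was at -0.618 on saline withdrawal day 15 replicate 2.

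In the deposited processed table, methamphetamine day 1 replicate 3 equals the mean of replicates 1 and 2 at all 45281 probes, with a largest difference of 7e-09. The mean of each of the 8 saline groups equals the naive mean within 6.7e-09, so saline against naive is 0 by construction there. Of its 78 columns 69 are independent. The rank correlation of a column with its own signals was at least 0.985 on the 60 arrays outside methamphetamine day 1, day 15 and the naive group. The median SD over arrays of the 15000 brightest probes was 0.0229, against 0.144 in the quantile-normalized signals. It holds 18 values above 16, the highest 21.22.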
